A study of Homo sapiens with 16 samples.

How the data were processed

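The series measured RNA from 3 human T-cell acute lymphoblastic leukaemia lines, CUTLL1, KOPTK1 and HPB-ALL (spelled Koptk1 and HpbALL in some of the labels). The target was lnrCXCR4, a long non-coding RNA (lncRNA) named for the chemokine receptor gene CXCR4. Per the labels' protocols it was targeted in either of 2 ways: lentivirus carrying CRISPR components, with a non-targeting guide as control, or an antisense oligonucleotide (ASO) added to the culture medium at 1 uM, with a scrambled oligonucleotide as control. Cells grew in RPMI with serum, total RNA was extracted with a column kit, and libraries were made with a strand-specific Illumina kit, per the labels' protocols. Which RNA was selected for sequencing and the time after treatment are not given in the sources used here.

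The 16 libraries form 5 experiments. CUTLL1 and KOPTK1 each had 1 control and 2 targeted libraries with guides, and again with ASOs. HPB-ALL had 2 control and 2 targeted libraries, with guides only. The titles number the 2 targeted libraries of an experiment as guide or ASO 1 and 2, while their descriptions call them replicates 1 and 2. They were read here as different guides or ASOs, which the labels do not settle, and were used as replicates. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

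The deposited table gives 57820 genes by symbol, with the Ensembl identifier before the symbol for 2344 of them, and its values are a signal in normalised read counts. The authors' column for each library holds whole reads divided by 1 factor: 100% of values in each column were whole multiples of its smallest nonzero value, within a tolerance of 1e-06. STAR (version 1.4.2), DESeq2 and the genome build hg19 are named per the submitters' processing notes, without their roles. The read counter, the gene annotation, the use of strand in counting and any filter are not given in the sources used here. Antisense and overlapping genes therefore cannot be told apart with certainty, and near-identical genes, such as those of the histone families, may share reads. Recovered totals ran from 34547469 to 72178929 reads per library. The reference annotation at hand was of another build than hg19, so no coordinates are given, and it served only for GC content and transcript length, matched by symbol.

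Tests used log2(normalised count + 1) in limma with empirical Bayes moderation and an intensity trend, over genes with a mean of 20 or more in the libraries of the fit, and an adjusted p (Benjamini-Hochberg) under 0.05 was the threshold. Fold changes on this scale understate those of low genes. The guide comparison took the 10 guide libraries with cell line as a term, the ASO comparison the 6 ASO libraries with cell line, and the joint comparison all 16 with experiment as a term. The 5 single experiments, the difference between the lines in the guide effect (an F test) and guides minus ASOs came from 1 fit of 10 group means over all 16 libraries. A lone control was there assumed to vary like the other groups. Guide 2 minus guide 1 used the 6 targeted guide libraries with cell line as a term. The tests, the gene lists and the rule for naming genes were chosen before the data were examined.

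Gene lists were tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, where at least 5 members could be tested, with Benjamini-Hochberg adjustment over the lists. The naming rule took, in each of the guide, ASO and joint comparisons, the 8 rising and 8 falling genes with the largest log2 fold change among calls in which every targeted library lay on the same side of its control. It took up to 4 members with the smallest p from each list past the threshold, up to 2 from each other list, 3 per direction from the single experiments, the 5 smallest p of the F test, and CXCR4 with its list of neighbouring genes throughout. Genes named outside this rule are given as list members or as chosen after their values were seen.

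Alternatives were another pseudocount (5), no filter or a mean of 100 or more, median-of-ratios or quantile scaling, robust moderation, the replicate number as a block, 1 guide or ASO number alone, leaving out each library, and edgeR's quasi-likelihood test and DESeq2 on recovered reads. The recovered-read tests left out the library of CUTLL1 with ASO 1, whose read step lies too near 1 for that step to be checked, and so used 15 libraries at most. Versions were R 4.3.3, limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0. Fisher's exact test and the expected overlap described calls shared between comparisons. The distance between 2 libraries was the mean chi-square per gene of their recovered reads, over genes with at least 50 reads in the pair, where 1 means counting noise alone.

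The tests were tested on simulated counts in which a known set of genes was changed. At a fold of 1.2, 1.5 and 2 the guide comparison recovered 57.6%, 83.3% and 89.2% of 66, 66 and 65 changed genes, with 1.18% of its calls false. The ASO comparison recovered 50.7%, 73.1% and 87.5%, with 0 false calls, and the joint comparison 66.7%, 88.1% and 90.8%, with 2.17% false. Guide 2 minus guide 1 recovered 59.7%, 65.7% and 82.3%, with 0 false. Guides minus ASOs recovered 33.3%, 74.6% and 75.4%, with 11.3% of its calls false, and the F test 28.8%, 53.7% and 78.8%, with 12.3% false. In the single experiments 6.38% to 29.5% of calls were false, which is above the 5% aimed for: 9 to 61 false calls, most of them in genes low in that experiment. With a mean of 20 or more in each experiment compared, the share was 0.758% to 9.64%, still above 5% with guides in KOPTK1 (5.1%) and HPB-ALL (9.64%). Calls in these 2, and calls of low genes in every single experiment, are therefore less certain than their p. The simulations changed far fewer genes than were called in the data, so their shares of false calls need not hold for the real calls. In the guide, ASO and joint simulations a changed gene had the same fold in every line. The real guide effect differed between the lines for 6130 of 14020 genes, so the recovered shares need not hold either.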

Results

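RNA was sequenced from 16 libraries of 3 T-cell acute lymphoblastic leukaemia (T-ALL) lines, 6 of them controls and 10 with the lncRNA lnrCXCR4 targeted by CRISPR guides or by ASOs. Guides were used in CUTLL1, KOPTK1 and HPB-ALL (4 control and 6 targeted libraries), and ASOs in CUTLL1 and KOPTK1 (2 control and 4 targeted libraries). Each library held 34547469 to 72178929 recovered reads over 57820 listed genes. Values below are the deposited normalised read counts, and fold changes are log2 fold changes of targeted against control libraries from limma, with a standard error (SE) and adjusted p. The guide controls of CUTLL1 and KOPTK1 and all ASO controls are single libraries, so those controls carry no SD.

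The first question is whether the targeted RNA fell. No entry of the table carries the name of the lncRNA (0 entries), so its own level was not analysed here and the labels of the targeted libraries are not checked by their target. CXCR4, the chemokine receptor gene for which the lncRNA is named, was higher than its control mean in 10 of 10 targeted libraries. In KOPTK1 it read 18309 in the guide control and 24452 ± 807 (SD, n = 2) with guides, and 17550 and 25024 ± 616 (SD, n = 2) with the ASO control and ASOs. In CUTLL1 it read 24920 and 26867 ± 382 (SD, n = 2) with guides, and 24422 and 27454 ± 650 (SD, n = 2) with ASOs. In HPB-ALL it read 31765 ± 868 in controls and 32722 ± 910 with guides (SD, n = 2 each). CXCR4 rose by 0.17 (SE 0.060, adjusted p 0.0303) in the guide comparison, 0.34 (SE 0.074, adjusted p 0.00671) in the ASO comparison and 0.23 (SE 0.054, adjusted p 0.00141) in both together. By experiment it rose by 0.42 (adjusted p 5.95e-06) and 0.51 (adjusted p 1.13e-06) in KOPTK1 with guides and ASOs, and by 0.11 (adjusted p 0.047) and 0.17 (adjusted p 0.00525) in CUTLL1. The HPB-ALL value, 0.04, did not pass (adjusted p 0.299), and the guide effect on CXCR4 differed between the lines (F 23.81, adjusted p 0.000822). The guide call for CXCR4 was lost with guide 1 alone (0.20, adjusted p 0.0712), with guide 2 alone (0.15, adjusted p 0.138). It was also lost without the KOPTK1 guide control (0.07, adjusted p 0.116), KOPTK1 guide 1 (0.14, adjusted p 0.0525) or KOPTK1 guide 2 (0.16, adjusted p 0.0587). The ASO call was lost with ASO 1 alone (0.34, adjusted p 0.0559), and the joint call when each line and arm counted once (0.22, adjusted p 0.11). The CUTLL1 guide call was lost without CUTLL1 guide 1 (0.09, adjusted p 0.154) or guide 2 (0.12, adjusted p 0.0696). Its fold of 0.11 also missed the threshold without CUTLL1 ASO 1 or ASO 2 (adjusted p 0.0571 each) and without KOPTK1 ASO 1 or ASO 2 (adjusted p 0.052 each), libraries that enter the shared fit.

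Genes that neighbour CXCR4 on the chromosome moved both ways. DARS, which encodes aspartyl-tRNA synthetase, fell by 0.55 with guides (SE 0.037, adjusted p 1.14e-06) and by 0.53 with ASOs, and SPOPL fell by 0.62 and 0.70. LCT, the lactase gene, fell by 0.71 with guides (adjusted p 0.00212) and by 0.71 with ASOs (adjusted p 0.0163). The DNA helicase subunit gene MCM6 rose by 0.41 and 0.39, RAB3GAP1 by 0.36 and 0.36, R3HDM1 by 0.31 and 0.36 and UBXN4 by 0.33 and 0.29. CCNT2 (0.05 and -0.12) and ZRANB3 (-0.15 and -0.11) did not pass, and the remaining listed neighbours were too low to test or not matched. CCNT2 passed in the ASO comparison with quantile scaling (-0.13, adjusted p 0.0402) and without CUTLL1 ASO 1 (-0.15, adjusted p 0.0251). It also passed by edgeR (-0.15, adjusted p 0.0198) and DESeq2 (-0.14, adjusted p 0.012), which left out that library too. ZRANB3 passed in the guide comparison without the CUTLL1 guide control (-0.36, adjusted p 0.0045), and its sign changed with quantile scaling (0.03 with guides). In single lines the guides gave opposite calls for ZRANB3, up in CUTLL1 (0.35, adjusted p 0.00564) and down in HPB-ALL (-0.50, adjusted p 8.85e-05). Of 10 tested members, CXCR4 included, 5 rose and 3 fell in each comparison (adjusted over the list alone, 5 and 3 with guides, 5 and 4 with ASOs). Camera called the list in neither comparison (adjusted p 0.58 and 0.736), and its guide median (0.11) and mean (-0.04) differed in sign. The ASO call of LCT was lost without the KOPTK1 ASO control (-0.31, adjusted p 0.138), without KOPTK1 ASO 1 (-0.66, adjusted p 0.0532) and without KOPTK1 ASO 2 (-0.65, adjusted p 0.0512). It was lost as well with ASO 1 alone (-0.72, adjusted p 0.0807), ASO 2 alone (-0.71, adjusted p 0.0919) and quantile scaling (-0.43, adjusted p 0.0901), and the call of UBXN4 with ASO 2 alone (0.27, adjusted p 0.0508).

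**Figure D1:**
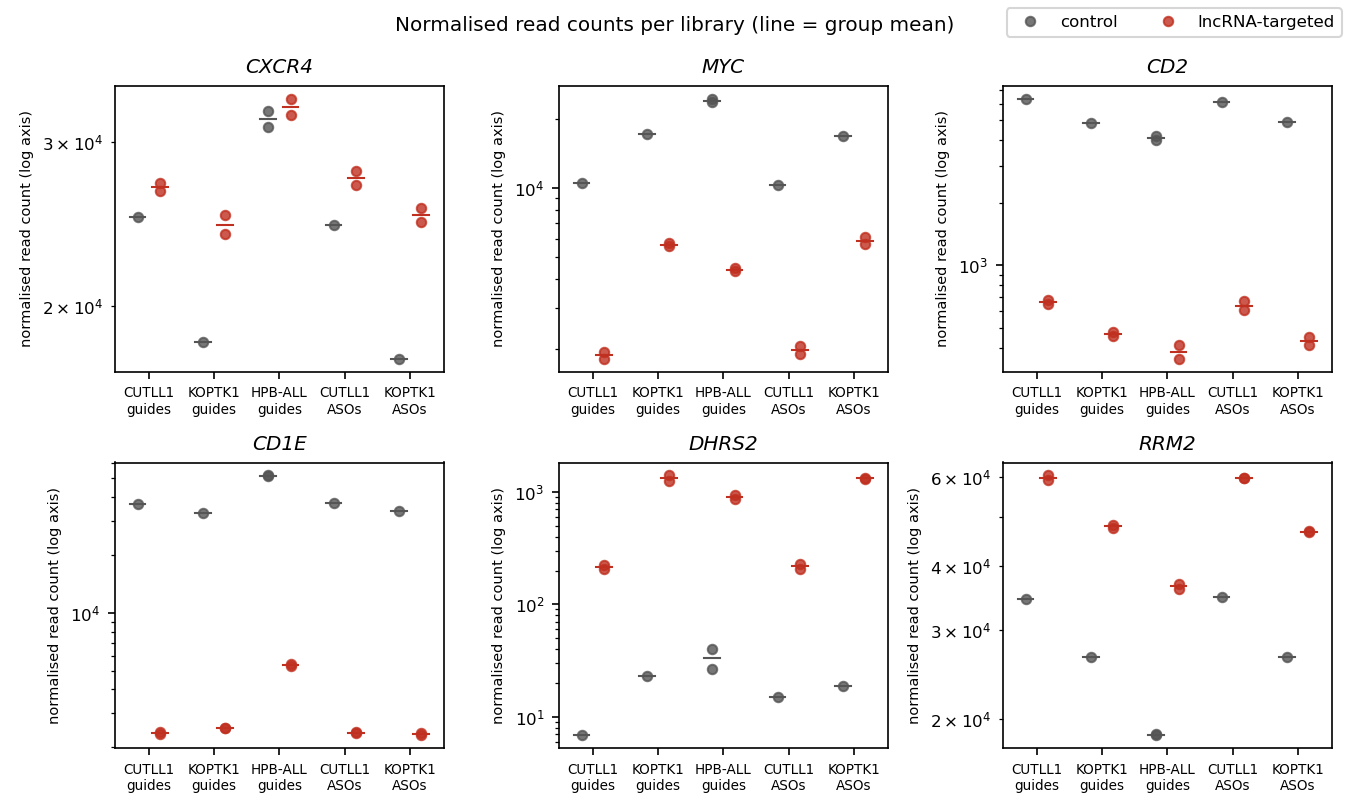
Normalised read counts of CXCR4, MYC, CD2, CD1E, DHRS2 and RRM2 in each library (log axes), by experiment, with controls in grey, targeted libraries in red and a line at each group mean. MYC, CD2 and CD1E lie lower and DHRS2 and RRM2 higher in the targeted groups than in their controls. CXCR4 differs less and is lowest in the KOPTK1 controls.

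The guide comparison asks what followed lentiviral CRISPR targeting in the 3 lines. Among lists with enough tested members for camera, the lowest median was that of T-cell receptor complex and thymocyte surface genes. CD2, an adhesion receptor of T cells, went from 6326 in the CUTLL1 control to 667 ± 24.3 (SD, n = 2) and from 4853 to 467 ± 17.2 in KOPTK1 (SD, n = 2). In HPB-ALL it went from 4114 ± 116 to 383 ± 41.0 (SD, n = 2 each), and its log2 fold change was -3.36 (SE 0.058, adjusted p 3.88e-09). CD1E, a CD1 family gene of cortical thymocytes, had a log2 fold change of -3.60 (SE 0.098), the recombinase gene RAG1 of -2.68 (SE 0.082) and the co-receptor gene CD8A of -1.79 (SE 0.053). Of 27 members 26 fell and 0 rose (27 fell adjusted over the list alone), with a median of -1.90 (camera adjusted p 4.28e-11, and adjusted p = 0.00497 with an estimated correlation).

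Genes of chemokine receptors and adhesion also fell with guides, 16 of 22 tested, while 2 rose, CXCR4 and the integrin gene ITGB1 (17 and 2 adjusted over the list alone). The integrin genes ITGA4 and ITGB2 were at -2.46 (SE 0.098) and -1.30 (SE 0.072), and the adhesion molecule genes ICAM1 and ICAM3 at -2.28 (SE 0.14) and -1.23 (SE 0.077). The median was -1.25 (camera adjusted p 0.000675, but adjusted p = 0.0671 with an estimated correlation). Of 20 tested T-lineage transcription factors 13 fell and 0 rose (13 adjusted over the list alone; camera adjusted p 0.00119, but adjusted p = 0.426 with an estimated correlation). The lymphoid regulator IKZF1 was at -2.10 (SE 0.095), GATA3 at -0.96 (SE 0.066), TCF3 at -0.80 (SE 0.057) and MYB at -0.78 (SE 0.048).

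MYC, the growth-promoting transcription factor that NOTCH1 switches on in T-ALL, fell by 2.21 with guides (SE 0.13, adjusted p 5.65e-07). It read 10466 in the CUTLL1 control and 1868 ± 90.0 with guides, 17124 and 5666 ± 138 in KOPTK1, and 23970 ± 520 and 4410 ± 95.0 in HPB-ALL (SD, n = 2 where given). IL7R, the interleukin-7 receptor gene, was at -2.56 (SE 0.058), the costimulatory receptor gene CD28 at -2.44 (SE 0.20) and DTX1, a NOTCH regulator, at -1.30 (SE 0.077). In all, 13 of 19 tested NOTCH1 targets fell and 1, HES4, rose (14 and 1 adjusted over the list alone). Their median was -0.92 (camera adjusted p 0.00162, but adjusted p = 0.0763 with an estimated correlation), and NOTCH1 itself did not pass (0.15, adjusted p 0.196). Of 25 ribosome biogenesis genes driven by MYC 24 fell (25 adjusted over the list alone), with a median of -0.81 (camera adjusted p 2.16e-08, but adjusted p = 0.426 with an estimated correlation). Among them were the nucleolar gene NOP16 (-1.24, SE 0.048), the spermidine synthase gene SRM (-1.11, SE 0.053), WDR12 (-0.81, SE 0.034) and TSR1 (-0.77, SE 0.033).

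Several groups were higher with guides. Of 25 mitosis genes 20 rose and 2 fell (the same counts adjusted over the list alone), with a median of 0.25 (camera adjusted p 0.000423, but adjusted p = 0.422 with an estimated correlation). Among them were the spindle and kinetochore genes DLGAP5 at 0.64 (SE 0.032), CENPE at 0.63 (SE 0.051), CDCA8 at 0.54 (SE 0.030) and NUSAP1 at 0.44 (SE 0.039). Of 23 cholesterol synthesis genes 16 rose and 2 fell (16 and 2 adjusted over the list alone; median 0.32, camera adjusted p 0.00162, but adjusted p = 0.431 with an estimated correlation). IDI1 was at 0.75 (SE 0.055), LSS at 0.74 (SE 0.050), SC5D at 0.59 (SE 0.048) and MVD at 0.52 (SE 0.039). Of 23 p53 targets 14 rose and 6 fell (14 and 6 adjusted over the list alone), among them the stress gene SESN1 at 1.82 (SE 0.12) and the repair gene XPC at 0.87 (SE 0.043). CCNG1 rose by 0.82 (SE 0.043) and the translesion polymerase gene POLH by 0.62 (SE 0.041), while MDM2, a negative regulator of p53, was at -0.27 and FAS, a death receptor gene, at -1.51. The p53 list passed (median 0.62, camera adjusted p 0.0372, but adjusted p = 0.426 with an estimated correlation), and not with quantile scaling (adjusted p 0.075) or a mean of 100 or more (adjusted p 0.0792).

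Lists on RNA quality and selection moved with targeting too. All 15 mitochondrially encoded genes rose with guides (15 adjusted over the list alone; median 0.32, camera adjusted p 0.000123, but adjusted p = 0.431 with an estimated correlation). The ribosomal RNA gene MT-RNR2 was highest (0.73, SE 0.061), with MT-ND5 at 0.40 (SE 0.039), MT-CYB at 0.37 (SE 0.039) and MT-CO1 at 0.32 (SE 0.039). Of 13 replication-dependent histone genes 12 rose (12 adjusted over the list alone; median 1.45, camera adjusted p 0.000736, but adjusted p = 0.431 with an estimated correlation). HIST2H2BE was at 2.41 (SE 0.13), HIST1H3H at 2.38 (SE 0.17), HIST1H2AG at 2.10 (SE 0.10) and HIST1H1C at 1.65 (SE 0.15). The shares of counts that follow pool the guide and ASO libraries of a line and arm, where both were made. Mitochondrial genes took 2.15% ± 0.037 (SD, n = 2) of counts in CUTLL1 controls and 2.51% ± 0.033 (SD, n = 4) in CUTLL1 targeted libraries. The shares were 2.46% ± 0.024 (n = 2) and 3.15% ± 0.11 (n = 4) in KOPTK1, and 1.84% ± 0.00071 (n = 2) and 2.51% ± 0.014 (n = 2) in HPB-ALL. Histone genes took 0.0198% ± 0.0014 in CUTLL1 targeted libraries against 0.0052% ± 0.00042 in controls, with the same numbers of libraries. In KOPTK1 they took 0.00522% ± 0.00068 against 0.00307% ± 0.00027, and in HPB-ALL 0.00798% ± 9e-05 against 0.00269% ± 5e-05.

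Among called genes that moved one way in all 6 guide libraries, the largest rises were in EFR3B (5.09, SE 0.44), the short-chain dehydrogenase gene DHRS2 (5.06, SE 0.19), 1 gene named only for its clone (5.03, SE 0.34) and DACT3 (4.20, SE 0.17). Next came the netrin receptor gene UNC5B (3.99, SE 0.21), ZCCHC24 (3.70, SE 0.097), the stress gene SESN3 (3.67, SE 0.24) and AP000692.10 (3.64, SE 0.25). DHRS2 went from 6.83 to 214 ± 11.5 in CUTLL1, from 23.3 to 1333 ± 96.7 in KOPTK1 and from 33.2 ± 9.59 to 911 ± 52.5 in HPB-ALL (SD, n = 2 where given). The largest falls were in RP5-1028K7.2 (-6.64, SE 0.45), TUSC5 (-5.49, SE 0.54), AC079612.2 (-5.20, SE 0.25) and the focal adhesion gene TNS4 (-5.19, SE 0.43). They were followed by the hexokinase-like gene HKDC1 (-5.08, SE 0.38), RGL4 (-5.04, SE 0.31), CCDC26 (-4.98, SE 0.43) and the growth factor gene BMP10 (-4.95, SE 0.50). For TUSC5, CCDC26, AC079612.2, BMP10 and RP5-1028K7.2 some targeted groups lay near or at 0, and UNC5B was listed at 0 in the KOPTK1 control, so that these fitted values depend on the pseudocount. TUSC5 read 368 in the KOPTK1 control and 1.19 ± 0.057 with guides (SD, n = 2). It read 13.5 ± 1.52 in HPB-ALL controls against a listed 0 in both guide libraries.

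The other lists did not pass in the guide comparison, and unless given, their counts were the same adjusted over the list alone. Of 24 type I interferon genes 9 rose and 12 fell (camera adjusted p 0.483), with OAS3, an antiviral RNA sensor gene, at -2.88 (SE 0.071) and STAT2 at 0.86 (SE 0.031). Of 25 S-phase genes 12 rose and 7 fell (adjusted p 0.198; 13 and 7 adjusted over the list alone), with the ribonucleotide reductase gene RRM2 at 0.89 (SE 0.036) and POLE at 0.61 (SE 0.037). Among 21 activation and immediate early genes 4 rose and 9 fell (adjusted p 0.198), with DUSP2 at -1.25 and NFKB1 at -1.04. Of 13 BCL2 family genes 5 rose and 4 fell (adjusted p 0.986), with MCL1 at 0.76 and BCL2L1 at -0.69. The ATF4 list had 4 up and 13 down of 23 (adjusted p 0.109), with TRIB3 at -2.29 and SLC7A5 at -0.67, and passed without the CUTLL1 guide control (adjusted p 0.0358). The chaperones of the endoplasmic reticulum had 5 up and 11 down of 22 (adjusted p 0.362), with SDF2L1 at -1.10 and CALR at -0.63. Hypoxia and glycolysis genes had 12 up and 4 down of 24 (adjusted p 0.198), with KDM3A at 0.89 and P4HA1 at 0.61. The FOXO-related list had 10 up and 5 down of 19 (10 and 6 adjusted over the list alone, adjusted p 0.198), with CCNG2 at 0.81. Nuclear genes of oxidative phosphorylation had 12 up and 9 down of 29 (adjusted p 0.483), with SDHA at 0.57, and heat shock genes 6 up and 7 down of 18 (adjusted p 0.908), with HSPB1 at -0.82 and HSPE1 at -0.65. Cytosolic ribosomal proteins had 16 up and 4 down of 35 (15 and 3 adjusted over the list alone, adjusted p 0.0569), with RPLP1 at 0.39 and RPLP0 at 0.32. They passed without the CUTLL1 guide control (adjusted p 0.0131), without CUTLL1 guide 2 (adjusted p 0.03) and without KOPTK1 guide 2 (adjusted p 0.0236).

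Markers of other cell types gave few testable genes. The B-lineage genes IGLL1 (-3.39), CD79B (-2.55) and CD79A (-1.49) and the cytotoxic genes CST7 (-2.75), PRF1 (-2.34) and NKG7 fell with guides (3 of 3 tested in each list, also adjusted over the list alone). So did 1 of 1 myeloid gene, AIF1 (-0.67), and 0 erythroid genes could be tested. Of 5 epithelial and fibroblast genes the cadherin gene CDH1 fell (-3.09, SE 0.57) and the filament gene VIM rose (0.37, SE 0.068), and the list did not pass (adjusted p 0.68).

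Across all genes, limma called 9519 of 14069 tested genes in the guide comparison, 4599 up and 4920 down, of which 542 up and 1606 down exceeded 2-fold. Of 23 lists 10 passed with the preset correlation and 1 with an estimated correlation. With quantile scaling 5522 rose and 4130 fell, the median of all genes moved from -0.03 to 0.07, and the list medians of BCL2 family and heat shock genes changed sign between scalings.

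**Figure D2:**
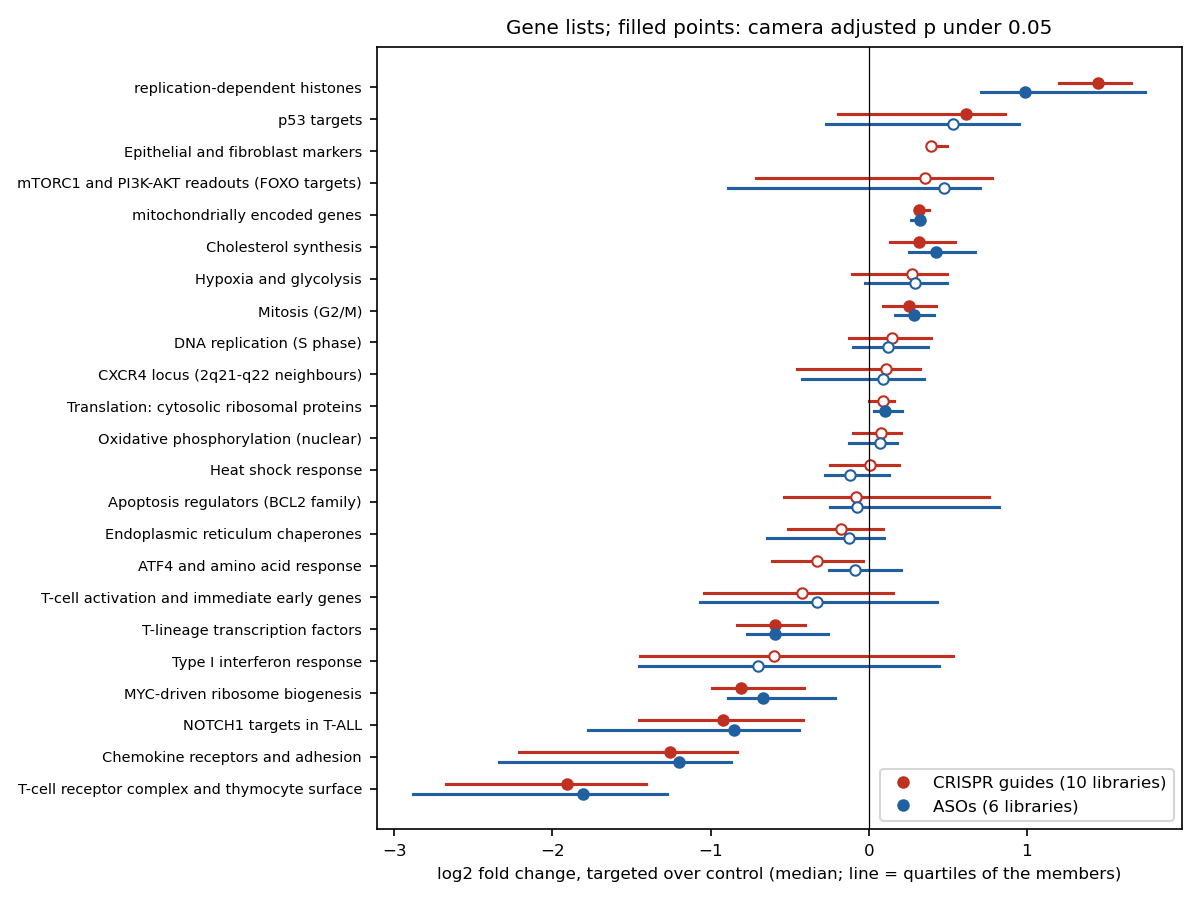
Median log2 fold change of each gene list (points, with bars from the lower to the upper quartile) in the guide and the ASO comparison, with filled points for lists past camera's threshold. The T-cell receptor and thymocyte surface list lies at -1.90 with guides and -1.81 with ASOs, and the histone list at 1.45 and 0.99.

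The ASO comparison asks the same of CUTLL1 and KOPTK1 with oligonucleotides. The same lists of T-cell and MYC-related genes were lower. CD1E fell by 3.91 (SE 0.040, adjusted p 2.47e-07), from 37374 to 2376 ± 20.1 in CUTLL1 and from 33763 to 2342 ± 48.4 in KOPTK1 (SD, n = 2 for ASOs). CD2 was at -3.38 (SE 0.081), RAG1 at -2.92 (SE 0.11) and ZAP70, a kinase of T-cell receptor signalling, at -1.12 (SE 0.031). Of 27 members 26 fell (26 adjusted over the list alone; median -1.81, camera adjusted p 6.47e-10, but adjusted p = 0.109 with an estimated correlation).

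Of 20 tested chemokine receptor and adhesion genes 16 fell and 2 rose with ASOs (16 and 3 adjusted over the list alone; camera adjusted p 0.000338, but adjusted p = 0.15 with an estimated correlation). The chemokine receptor gene CCR8 read 439 in the KOPTK1 ASO control and 4.43 ± 1.31 with ASOs (SD, n = 2), and 67.9 in the CUTLL1 control against a listed 0 in both ASO libraries. The adhesion molecule gene ICAM2 was at -0.84 (SE 0.043), and the integrin gene ITGAL fell as well. Of 17 T-lineage transcription factors 13 fell (13 adjusted over the list alone; camera adjusted p 0.000458, but adjusted p = 0.15 with an estimated correlation). They included IKZF1 at -1.88 (SE 0.057), GATA3 at -0.77 (SE 0.076), MYB at -0.68 (SE 0.033) and TCF3 at -0.65 (SE 0.027). Among 19 NOTCH1 targets 14 fell and 0 rose (14 adjusted over the list alone; camera adjusted p 0.000486, but adjusted p = 0.213 with an estimated correlation). CD28 was at -2.85 (SE 0.12), IL7R at -2.50 (SE 0.054), SORBS3 at -2.13 (SE 0.14), MYC at -1.95 (SE 0.18) and RASGRP1 at -0.85 (SE 0.059). Of 25 ribosome biogenesis genes 22 fell (22 adjusted over the list alone; median -0.67, camera adjusted p 1.79e-07, but adjusted p = 0.15 with an estimated correlation). They included MYBBP1A at -1.17 (SE 0.046), SRM at -0.90 (SE 0.044), TSR1 at -0.73 (SE 0.032) and NOLC1 at -0.57 (SE 0.027).

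With ASOs 19 of 25 mitosis genes rose and 1 fell (19 and 1 adjusted over the list alone; median 0.29, camera adjusted p 2.47e-05, but adjusted p = 0.15 with an estimated correlation). They included CDCA8 at 0.63 (SE 0.043), DLGAP5 at 0.58 (SE 0.030), CENPE at 0.57 (SE 0.044) and NUSAP1 at 0.46 (SE 0.026). Of 23 cholesterol synthesis genes 20 rose and 2 fell (20 and 2 adjusted over the list alone; median 0.43, camera adjusted p 2.47e-05, but adjusted p = 0.15 with an estimated correlation). They included INSIG1, MVK at 0.99 (SE 0.055), IDI1 at 0.75 (SE 0.037) and MVD at 0.57 (SE 0.034). All 15 mitochondrially encoded genes rose (15 adjusted over the list alone; median 0.33, camera adjusted p 0.000243, but adjusted p = 0.359 with an estimated correlation), with MT-RNR2 at 0.56 (SE 0.043). That list missed the threshold with quantile scaling (adjusted p 0.0627). Of 12 histone genes 7 rose (7 adjusted over the list alone; median 0.99, camera adjusted p 0.0132, but adjusted p = 0.647 with an estimated correlation), with HIST1H3H at 2.35 (SE 0.20). The histone list missed the threshold without the CUTLL1 ASO control (adjusted p 0.0652). Of 35 ribosomal protein genes 19 rose and 1, RPL22, fell (19 and 1 adjusted over the list alone), with RPLP0 at 0.38 (SE 0.033). Their median of 0.10 passed with the preset correlation (adjusted p 0.0046, but adjusted p = 0.647 with an estimated correlation). It did not pass with quantile scaling (adjusted p 0.826) or without the KOPTK1 ASO control (adjusted p 0.0637).

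The p53 list, with 13 up and 6 down of 23, did not pass with ASOs (camera adjusted p 0.0551), although XPC rose by 0.88 (SE 0.043) and SESN1 by 1.41 (SE 0.069). It passed without CUTLL1 ASO 1 (adjusted p 0.0452), without the KOPTK1 ASO control (adjusted p 0.0369) and without KOPTK1 ASO 1 (adjusted p 0.0488). Hypoxia and glycolysis genes, 11 up and 4 down of 24 with BNIP3L at 1.06 and KDM3A at 0.83, did not pass (adjusted p 0.053). They passed without the CUTLL1 ASO control (0.0176), CUTLL1 ASO 1 (0.035), CUTLL1 ASO 2 (0.0445) or KOPTK1 ASO 2 (0.048). S-phase genes (14 and 6 of 25, adjusted p 0.0651) passed without the CUTLL1 ASO control (0.0412) or CUTLL1 ASO 1 (0.0452), and chaperones (5 and 11 of 22, adjusted p 0.102) without the CUTLL1 ASO control (0.0314). In the BCL2 family 6 rose and 4 fell of 13 (adjusted p 0.787), with MCL1 at 0.65 and BCL2L1 at -0.68. Interferon genes (8 up and 13 down of 24, adjusted p 0.513), ATF4 genes (6 and 10 of 23, 0.366) and activation genes (5 and 10 of 21, 0.456) did not pass. Nor did oxidative phosphorylation genes (12 and 8 of 29, 0.456), heat shock genes (5 and 7 of 18, 0.456) and FOXO-related genes (11 and 6 of 19, 0.243). Adjusted over the list alone, the counts differed for S-phase (14 and 7), activation (6 and 10), oxidative phosphorylation (13 and 9) and heat shock genes (5 and 8). The B-lineage and cytotoxic markers fell again (3 of 3 tested in each), as did AIF1, by 0.57. The collagen gene COL1A1 (1.36, SE 0.35, adjusted p 0.0131) and VIM (0.39, SE 0.11, adjusted p 0.0158) rose, and the list had too few tested members for camera. Both calls were lost with ASO 1 alone (1.45, adjusted p 0.0827 for COL1A1; 0.38, adjusted p 0.0712 for VIM) and with ASO 2 alone (1.27, adjusted p 0.0708; 0.40, adjusted p 0.0627), at folds near those of the whole comparison. That of COL1A1 was lost without the KOPTK1 ASO control (0.81, adjusted p 0.0794).

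The largest rises with ASOs were in DPYSL3 (5.23, SE 0.62), DHRS2 (4.92, SE 0.46), EFR3B (4.60, SE 0.52), the clone-named gene (4.58, SE 0.49), BAIAP3 (4.30, SE 0.22), DACT3 (4.16, SE 0.20), TPPP (4.11, SE 0.42) and UNC5B (3.89, SE 0.18). DPYSL3 was listed at 0 in the CUTLL1 ASO control, and TPPP and UNC5B in the KOPTK1 ASO control. The largest falls were in TUSC5, CCR8, GPA33 (-5.50, SE 0.60), SCEL (-5.41, SE 0.76), the chemokine receptor gene CCR2, CCDC26, PIK3AP1 (-5.22, SE 0.67) and RP11-157N3.1 (-5.14, SE 0.52). TUSC5 read 340 in the KOPTK1 ASO control and 0.438 ± 0.619 with ASOs, CCR2 246 in CUTLL1 and 2.53 ± 0.753, and CCDC26 106 in KOPTK1 and a listed 0 in both ASO libraries (SD, n = 2). The call of CCDC26 was lost with DESeq2, which left out CUTLL1 ASO 1, at a larger fold of -8.05 (adjusted p 0.107). limma called 8913 of 13712 tested genes, 4359 up and 4554 down, and 525 up and 1431 down exceeded 2-fold. With quantile scaling 5109 rose and 3918 fell. Of 22 lists 10 passed with camera's preset correlation and 0 with an estimated one (smallest adjusted p 0.109), and fry called 16. Median signs of oxidative phosphorylation and activation genes changed between scalings.

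Guides and ASOs were compared to learn whether both moved the same genes. Fold changes correlated across 13437 genes tested in both (r 0.9326, rho 0.9241; genes are not independent replicates). Of genes called in both, 3844 rose in both against 1460 expected of independent lists, 3983 fell in both against 1576 expected, and 0 were called in opposite directions. Within a line r was 0.9281 in CUTLL1 and 0.9198 in KOPTK1, and between lines 0.6956 to 0.7637. In the single experiments, 11 of 7841 genes called with both in CUTLL1 and 19 of 7778 in KOPTK1 had opposite directions. The test of guides minus ASOs in CUTLL1 and KOPTK1 called 0 of 14020 genes by limma, with 1393 at an unadjusted p under 0.05, and no other tool was run for it. With no filter it called 1501 of 34609 genes, at a median mean count of 0.061, and 81 of them had a mean of 20 or more. Guide 2 minus guide 1 gave 0 calls of 13718, with 2193 at an unadjusted p under 0.05, and CXCR4 at -0.05 (adjusted p 0.277). A missing call does not show equal effects, and the guide and ASO libraries of a line and arm differed little. Their mean chi-square per gene was 1.74 to 14.6 over 10 pairs (median 4.28), against 2.35 to 6.77 over 6 replicate pairs (median 3.93). Without CUTLL1 ASO 1, whose read step could not be checked, these ranges were 2.29 to 14.6 over 8 pairs and 2.57 to 6.77 over 5.

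**Figure D3:**
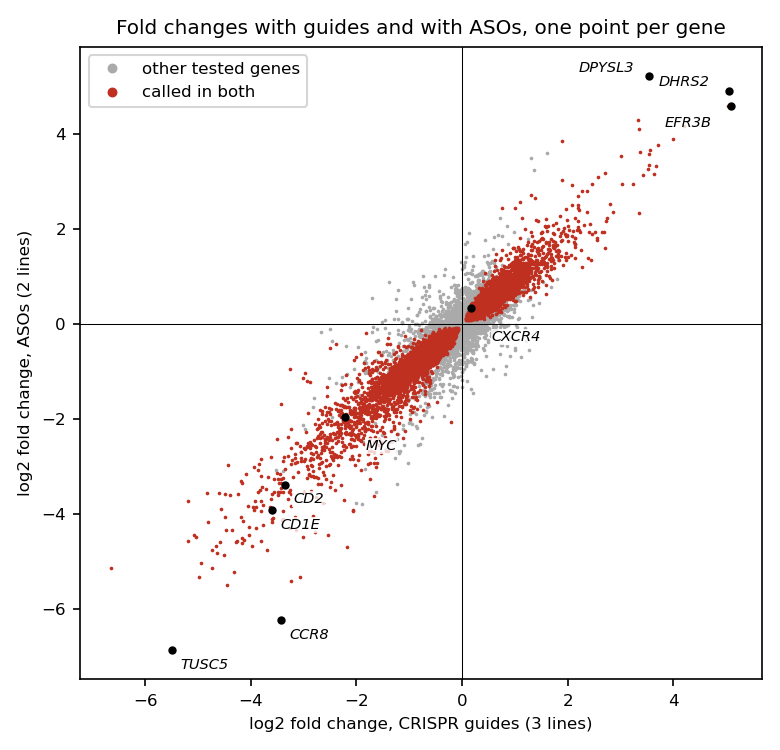
Log2 fold change of each gene with guides (horizontal axis) and with ASOs (vertical axis), in red where called in both comparisons and with 9 genes named. No gene called in both lies in the opposite quadrants, and CXCR4 lies near the centre at 0.17 and 0.34.

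**Figure D4:**
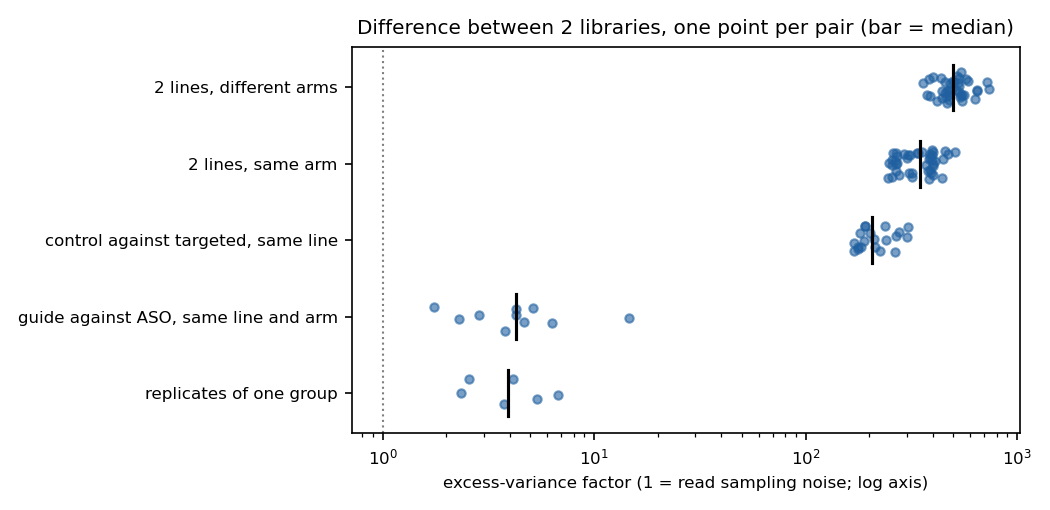
Mean chi-square per gene between 2 libraries, the excess-variance factor of the axis (log scale, 1 for read sampling noise), one point per pair and a bar at the median of each kind of pair. Guide and ASO libraries of a line and arm lie at a median of 4.28, replicates at 3.93, and control against targeted libraries of a line at 206.

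The joint comparison of all 16 libraries called 10514 of 14020 genes, 5076 up and 5438 down, and with quantile scaling 6045 up and 4590 down. DHRS2 (5.01, SE 0.23), EFR3B (4.91, SE 0.37), the clone-named gene (4.87, SE 0.31), DACT3 (4.19, SE 0.13), DPYSL3 (4.16, SE 0.50), UNC5B (3.95, SE 0.15), ZCCHC24 (3.73, SE 0.10) and BAIAP3 (3.68, SE 0.24) rose most. RP5-1028K7.2 (-6.09, SE 0.39), TUSC5 (-5.99, SE 0.45), CCDC26 (-5.10, SE 0.38), BMP10 (-4.98, SE 0.37), TNS4 (-4.97, SE 0.34), RP11-157N3.1 (-4.88, SE 0.26), HKDC1 (-4.85, SE 0.28) and RGL4 (-4.84, SE 0.22) fell most. Of 22 lists 11 passed, 6 up and 5 down, the p53 list among them (adjusted p 0.0408). That list missed the threshold with quantile scaling (adjusted p 0.0934), a mean of 100 or more (adjusted p 0.0682) or without the CUTLL1 guide control (adjusted p 0.0544). The ribosomal protein list (adjusted p 0.0175) missed it with quantile scaling (adjusted p 0.872). With an estimated correlation 2 passed, both of genes that fell. In the T-cell receptor and thymocyte surface list 26 of 27 fell (27 adjusted over the list alone, adjusted p = 0.000353). Among chemokine receptor and adhesion genes 19 of 22 fell and 2 rose (19 and 2 adjusted over the list alone, adjusted p = 0.022). When the libraries of a line and arm were averaged to 1 value, 6931 genes were called. In the 5 single experiments 2769 genes rose and 2921 fell in every one.

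Single experiments had 8736 calls in CUTLL1 with guides, 8737 in CUTLL1 with ASOs, 8982 and 8889 in KOPTK1, and 9941 in HPB-ALL, each of 14020 genes. In CUTLL1 the nuclear receptor gene PPARG read 629 in the guide control and 4.66 ± 1.23 with guides, and 689 and 3.04 ± 1.48 with ASOs (SD, n = 2). CD93 was at -6.04 with guides and -6.18 with ASOs (SE 0.36), and RASD2 rose by 4.75 with guides (SE 0.27). In KOPTK1 the PIWI family gene PIWIL3 read 309 in the guide control and a listed 0 in both guide libraries, and TPPP a listed 0 in the control and 35.9 ± 8.45 with guides. FGD5 went from 505 in the ASO control to 3.07 ± 4.34 with ASOs (SD, n = 2). In HPB-ALL C14orf37 rose by 4.94 (SE 0.41) and CTD-2083E4.7 was at -6.49 (SE 0.40). SLC38A1, an amino acid transporter gene, fell by 6.44 (SE 0.048) there, from 4811 ± 10.2 to 54.5 ± 3.08 (SD, n = 2 each).

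The guide effect differed between the 3 lines for 6130 of 14020 genes by limma's F test. SLC38A1 was at -0.72 in CUTLL1, -1.05 in KOPTK1 and -6.44 in HPB-ALL (F 3908). The thymocyte homing receptor gene CCR9 rose in KOPTK1, from 6605 to 17475 ± 51.2 (SD, n = 2), and fell by 1.25 in HPB-ALL. It did not pass in CUTLL1 (0.03, adjusted p 0.484; F 1293). SOGA2 rose by 2.46 in CUTLL1 and 0.42 in KOPTK1 and fell by 1.44 in HPB-ALL (F 877.5), and the fatty acid desaturase gene FADS1 rose by 0.58 in KOPTK1 and was at -0.20 in CUTLL1 and -1.21 in HPB-ALL (F 827.2). LCK, the kinase of T-cell receptor signalling, fell in CUTLL1 (-2.58), KOPTK1 (-1.67) and HPB-ALL (-3.34, F 778.5). Of the 6130 genes, 1410 rose in all 3 lines and 1553 fell in all 3, so that they differed in size, and 651 were called up in 1 line and down in another. CUTLL1 and KOPTK1 had a single guide control each. The homeobox gene TLX3, named after its values were seen, read 8261 ± 697 in HPB-ALL controls (SD, n = 2) and at most 5.87 in a control of the other lines.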

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

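The test of a difference between lines was planned, while the filter within each experiment was chosen only after results were seen. The guide effect differed between CUTLL1, KOPTK1 and HPB-ALL for 6130 of 14020 genes by limma's F test, and these results are given here because the same contrast gave unlike effects in the lines. The 5 genes with the smallest p were SLC38A1 (F 3908), CCR9 (F 1293), SOGA2 (F 877.5), FADS1 (F 827.2) and LCK (F 778.5). SLC38A1 was at -0.72, -1.05 and -6.44 in CUTLL1, KOPTK1 and HPB-ALL. CCR9, SOGA2 and FADS1 were called up in 1 line and down in another, while LCK fell in all 3. CXCR4 differed as well (F 23.81, adjusted p 0.000822), at 0.11 in CUTLL1, 0.42 in KOPTK1 and 0.04 in HPB-ALL.

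CUTLL1 and KOPTK1 rest on 1 guide control each. Their guide and ASO controls differed by a mean chi-square per gene of 2.292 in CUTLL1 and 4.276 in KOPTK1, against 2.345 to 6.77 between replicates and 245.5 or more between 2 lines of the same arm. This argues against an odd lone control library as the source, while an oddity of a culture shared by both controls stays open. The ASO controls of these lines gave CXCR4 folds of 0.17 and 0.51. Otherwise no technical or biological explanation of the differences between lines was tested. In simulated counts 12.3% of the calls of this F test were false (15 calls). Far fewer genes were changed there than were called here, so that share need not hold for these calls. With a mean of 20 or more in each experiment compared 5845 genes were called.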

How the results depend on the processing

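Counts with each line and arm averaged to 1 value, the removal of the trend in GC content and length, the fit without HPB-ALL, and the filter within each experiment were chosen after seeing the data. Of the alternatives to a count or a main value, 435 stayed the same, 18 were weaker and 6 were stronger. A count of called genes or lists stayed the same when it lay within a fixed factor of its main count. A CXCR4 value did so when it kept its direction and side of the threshold, and 0 reversed. The correlation of guides and ASOs did so when it moved by less than the SD between pairs of experiments. For single named genes 6791 values kept their direction and side of the threshold, 16 lost the call, 6 gained it and 0 reversed. Another 7 values without a call moved.

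CXCR4 lost its guide call with guide 1 only (0.20, adjusted p 0.0712) and guide 2 only (0.15, adjusted p 0.138), and its ASO call with ASO 1 only (0.34, adjusted p 0.0559), where fewer libraries were fitted. Leaving out 1 library gave 0.069 to 0.20 with guides (adjusted p 0.0217 to 0.116), 0.17 to 0.51 with ASOs and 0.17 to 0.26 jointly. The guide call was lost without the KOPTK1 guide control (0.069, adjusted p 0.116), KOPTK1 guide 1 (0.14, adjusted p 0.0525) and KOPTK1 guide 2 (0.16, adjusted p 0.0587). In CUTLL1 with guides the call was lost with no filter (0.11, adjusted p 0.126; 34609 genes tested), and leaving out 1 library gave 0.094 to 0.12 (adjusted p 0.035 to 0.154). It was lost there without CUTLL1 guide 1 (0.094), CUTLL1 guide 2 (0.12), either CUTLL1 ASO library or either KOPTK1 ASO library (0.11 each). With 1 value per line and arm the joint fold was 0.22 (adjusted p 0.11) and 6931 genes were called, 6921 of them shared with the 10514 calls, from fewer values.

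Guides minus ASOs had 0 calls by limma (1393 at an unadjusted p under 0.05), 1 with a pseudocount of 5, and 1501 of 34609 genes with no filter, of which 81 had a mean of 20 or more. The median mean count of these 1501 genes was 0.061, so many of them held almost no reads. The cause was not tested. Leaving out 1 library gave 0 to 4, the latter without CUTLL1 ASO 2. Lists past camera's threshold went from 10, 10 and 11 with guides, with ASOs and jointly to 1, 0 and 2 with an estimated correlation, which replaces the preset one by each list's own.

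Leaving out 1 library, the guide comparison had 8935 to 9333 calls, the ASO comparison 7989 to 8934 and the joint one 10220 to 10460. The lists past camera numbered 10 to 12, 10 to 13 and 10 to 11. By edgeR and DESeq2 the counts were 10045 and 9842 with guides, 8388 and 7853 with ASOs, and 10838 and 10600 jointly. The ASO and joint counts of these tools left out CUTLL1 ASO 1, so they differ from limma's in libraries as well. Quantile scaling called 9652 genes with guides, 5522 up and 4130 down, so the balance of directions depends on scaling. Removal of the GC and length trend called 9140, 5566 up and 3574 down. That fit held only the 12725 annotated genes, among which the main fit had 8801 calls. With the replicate number as a block there were 9188, 7301 and 10275 calls, and 10722 in HPB-ALL alone against 10482 without the block. Deviations of libraries with 1 number correlated at -0.0139 to 0.0655, so no strong pairing by number was seen. A weaker shared effect cannot be excluded by such correlations.

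The 10 fits that would leave out a lone control of the experiment tested could not be made. Depth limits genes listed near 0, where a few reads decide a fold.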

Other observations

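The tests of other splits for guide 2 minus guide 1, of the BET-responsive genes already seen, of shared cultures, of exchanged labels, of the mitochondrial genes and of the histones with ASOs were chosen only after the result was seen. The histone test was written before its result but first named histone and mitochondrial genes together, and was narrowed to histones and to the guide comparison afterwards.

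The first pattern is the number of genes that differ between control and targeted libraries, 9519 of 14069 with guides and 10514 of 14020 jointly. Among 54 splits of the guide libraries within lines 1, the real one, gave as many calls (highest other 12). Among 100 drawn splits of all libraries 1 did (highest other 7296, of 486 possible). This argues against a chance division of these libraries into arms. The splits cannot judge chance differences between cultures, since nothing in the labels says that the libraries came from separate cultures. For guide 2 minus guide 1 there are 4 splits, too few for a share under 0.05; all 4 gave as many calls as the real 0 (highest other 0). A trend in GC content and length does not account for the whole, since 88.86% of the annotated guide calls were still called in the same direction after it was removed. The labels name the targeting of the lncRNA as the difference between the arms. Its effect stays open, because no entry carries the name of the lncRNA and its level was not analysed here.

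A hypothesis from the data is that the targeted libraries may carry the profile of a BET bromodomain inhibitor or a state like it, since with guides HEXIM1 (2.12), SERPINI1 (2.08) and HIST2H2BE (2.41) rose and MYC (-2.21), IL7R (-2.56) and BCL2 (-1.28) fell. Of 11 listed genes already seen, 11 were called in the listed direction with guides and 10 with ASOs, which decides nothing because they were chosen for the pattern. Of 4 tested genes not yet looked at, 4 were with guides: CDK6 (-0.61), TERT (-1.97), HIST1H2BJ (2.14) and HIST1H2BD (2.23), with CD180 and FOSL1 too low to test. HIST1H2BK and HIST1H2BG were moved to the seen genes after their values were known, the H2B genes move together, and 32.69% of all genes tested with guides were called up and 34.97% down, so 4 genes are weak evidence. A label exchanged between the arms of a line is argued against: 2 libraries of a line and arm differed by a mean chi-square per gene of at most 14.57, and control against targeted libraries of a line by at least 168.4. Another treatment, an exchange of the arms in every line and loss of MYC by another route stay open, since no library was checked by its target.

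The second pattern is the closeness of guide and ASO libraries of a line and arm. Their median chi-square per gene was 4.282 over 10 pairs, within the 2.345 to 6.77 between replicates. Apart from the HPB-ALL controls (2.567), these replicates carried different guides or ASOs by their titles. If so, that range holds such differences too and is a lenient yardstick. The closest pair, CUTLL1 guide 1 and CUTLL1 ASO 1, had 1.743 over 12941 genes. That pair rests on a library whose read step could not be checked, and without it the guide and ASO pairs lay at 2.292 to 14.57 (median 4.282, 8 pairs) and replicates at 2.567 to 6.77. Separate lentiviral and oligonucleotide experiments would be free to differ by more, so shared cultures or RNA are a candidate explanation. Each pair lay above counting noise, so the libraries were counted separately. If cultures were shared, guides and ASOs are not independent evidence, and experiments that truly gave like effects stay open.

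The third pattern is the rise of histone and mitochondrial genes. If more non-polyadenylated RNA had been kept in the targeted libraries, small non-polyadenylated RNAs would rise with the histones, but with guides their median was 0.605 and their upper quartile 0.9165, under the histones' lower quartile of 1.204 (median 1.449). With ASOs their median was 0.203 and their upper quartile 0.2921, under the histones' lower quartile of 0.7081 (median 0.9864). This argues against it as the whole cause for the histones over the lines, while 5 of 11 small RNAs rose and 0 fell with guides by limma. The most abundant, RN7SL2 (1.27) and RN7SL1 (1.21), lay above the histones' lower quartile of 1.204 and the other tested ones below it, so a part may remain. In KOPTK1 alone the explanation stays open, since the small RNAs' upper quartile of 0.7319 with guides and 0.277 with ASOs exceeded the histones' lower quartile of 0.4256 and 0.2006. With ASOs there the small RNAs' median of -0.07, with 0 of 11 called up, against the histones' 0.4454, with 5 of 13, goes against it, but the quartiles overlap. For the mitochondrial genes the explanation also assumes that their RNAs are non-polyadenylated, which was not checked. With guides, at their median of 0.32, it cannot be told apart from other causes, because their rise lies within that of the small RNAs. With ASOs their median of 0.325 lay above the small RNAs' upper quartile of 0.2921. This goes against it and met the bound used with guides, a median above that quartile. For ASOs a stricter bound, a lower quartile above it, was set after these values were known. Their lower quartile of 0.2675 did not meet it, so the explanation stays open there as well.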
